A study of Mus musculus with 4 samples.

How the data were processed

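Tumor-initiating hepatocytes of C57BL/6 mice carrying a control short hairpin RNA or one against the long noncoding RNA H19 were profiled in 4 libraries. Each condition had 1 mRNA library and 1 small RNA library, so each of the 4 groups held 1 library. The mRNA tables hold raw counts per gene symbol as the authors deposited them. Reads were trimmed and mapped to GRCm38 with STAR 2.5.2b, per the series' design text, and the submitters' processing notes also name Trimmomatic 0.36. The counting program and gene annotation are not given in the sources used here. Both mRNA tables list the same 16211 symbols, and the lowest summed count of a listed gene was 21. In 37 symbols inserted apostrophes were removed, and 14962 symbols were found in the reference tables. Strand use in counting is not stated, so overlapping and antisense genes cannot be told apart here.

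For small RNA, reads of 15 to 31 nucleotides were kept and searched against miRBase 21, per the series' design text. The deposited small RNA tables hold raw counts with 1 line per precursor, split into a 5' arm, a 3' arm and reads outside both arms. The column named expression values was identical to the 5' arm column in every line, so it leaves out the 42.0% of arm reads of the control library and 43.6% of the library labelled H19 knockdown that lie in the 3' arm column. Both arm columns were therefore used. Reads matching several precursor copies are counted at each copy, so each of the 91 arms with more than 1 copy was taken from the copy with the most reads. An arm is named by its precursor and its arm column.

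Counts were scaled with edgeR 4.0.16 TMM effective library sizes in R 4.3.3. For each gene or arm the log2 ratio of the library labelled H19 knockdown over control was computed with 1 count added to each scaled count, together with an exact conditional binomial 95% interval. These intervals cover counting error only, and reads copied by PCR are not independent molecules. With 1 library per group there is no estimate of the spread between cultures, so no p-value was computed and no difference has a replicate check. Genes or arms with at least 100 reads in at least 1 library and a 2-fold ratio were counted. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

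Gene and miRNA lists and the rule for named genes were fixed before the data were examined. Members with at least 20 reads summed over both libraries entered a list. The median log2 ratio of each list with at least 5 measured members was placed among 10000 random lists of the same size drawn from the same 20 bins of mean expression. A list was called outside the random range at or below the 2.5 or at or above the 97.5 percentile, and this describes these libraries only. The text names H19 and miR-675, then from the 12 highest and 12 lowest ratios among features with at least 100 reads, leaving out predicted and clone-named models, pseudogenes and small RNA genes of the mRNA table. It also draws on up to 4 members per list with the largest absolute log2 ratio and at least 100 reads, let-7 arms with at least 1000 reads, and the 10 miRNAs with the most reads. Other genes are marked as chosen after their values were seen. Some genes that the rule names are not reported here. Genes were placed on GRCm38 chromosomes by symbol for 90.2% of symbols with a RefSeq gene table.

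The ratios, intervals and calls were tested on simulated data that held counting error only, with library totals in place of TMM sizes. The test therefore covers neither the spread between cultures nor the scaling. Poisson counts were drawn for the 16211 genes of the mRNA comparison, with 200 genes altered. Of the 11139 unaltered genes with at least 100 reads 0 were called, and 95.2% of true ratios lay inside the interval. Of the 100 genes altered 3-fold 100.0% were called, and of the 100 altered exactly 2-fold 53.0% were called. For the 889 arms of the miRNA comparison 147 were altered, 0 of 153 unaltered arms were called, 100.0% of 73 arms altered 3-fold and 47.9% of 73 altered 2-fold were called, and 96.3% of ratios lay inside the interval.

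Alternatives were scaling to the total count, DESeq2 1.42.0 size factors, TMM without the 10 most counted features, 5 or 0.5 counts added, other count minimums, a 1.5-fold limit, intervals wholly beyond 2-fold, the mean in place of the median and 10 expression bins. Subtracting chromosome medians, other read columns of the small RNA tables and leaving out precursors with over 50% of reads outside their arms were chosen after seeing the data.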

Results

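The data comprised raw read counts from tumor-initiating hepatocytes, cells named by the labels for their capacity to start tumors, with a control hairpin or a hairpin against H19. The mRNA libraries held 33578868 reads in the control and 34061172 in the library labelled H19 knockdown, over 16211 listed genes, of which 11412 had at least 100 reads in 1 library. The small RNA libraries held 7105897 and 10483889 reads on mature arms. A total of 295 of 889 arms had at least 100 reads in 1 library. Each condition had 1 library per assay, so no difference has a replicate check.

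The targeted gene was compared first, to check the labels. H19, an imprinted long noncoding RNA on chromosome 7 at 142575530 to 142578146 in GRCm38, had 43 reads in the control and 40 reads in the library labelled H19 knockdown. The ratio was 0.931, with a 95% counting interval of 0.589 to 1.46. H19 was thus not measurably lower in the library labelled H19 knockdown. The interval, which covers counting error only, excluded a reduction to 0.5 of the control. Every direction given below refers to that label, which the H19 counts did not bear out. No read of miR-675, the miRNA hosted by H19, was listed in either small RNA table, which allows up to 3 reads in each library. Igf2, the imprinted neighbor of H19, as well as Dlk1, Meg3, Cdkn1c, Sox2, Nanog and Pou5f1 were members of the fixed lists and were not listed.

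The mRNA comparison asked which transcripts differ with the H19 hairpin. Of 11412 genes, 23 were at least 2-fold higher and 12 at least 2-fold lower in the library labelled H19 knockdown. En1, a homeobox transcription factor, had the highest ratio, with 24 and 101 reads and a ratio of 4.08 (interval 2.67 to 6.86). Elfn1 followed with 38 and 122 reads (ratio 3.15), Megf10 with 55 and 156 (ratio 2.80), Gfra1, a co-receptor for GDNF, with 62 and 159 (ratio 2.54) and Eml1 with 53 and 133 (ratio 2.48). Crtap, part of the collagen prolyl 3-hydroxylation complex, was 2.41-fold higher (2.05 to 2.85). Lamb1, a laminin chain of basement membranes, had 791 and 1885 reads, a ratio of 2.38 (2.19 to 2.59). Cldn1, a tight junction protein, was at a ratio of 2.34, Sorcs2 at 2.27, Hunk at 2.25, Flrt2 at 2.23 and Prrx1 at 2.15.

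The lowest ratio belonged to Lyz2, a lysozyme of myeloid cells, with 132 and 53 reads (ratio 0.406, interval 0.286 to 0.556). Atp9a was at 0.427, Gbp4, an interferon-inducible GTPase, at 0.442 with 451 and 199 reads, Camta1 at 0.450 and Ch25h, cholesterol 25-hydroxylase, at 0.469. Ifi27 was at 0.470, Ankrd33b at 0.472, Gpr176 at 0.476, the acute phase gene Saa1 at 0.483, Tnxb at 0.487 and Il13ra2, a decoy receptor for interleukin 13, at 0.488. In 6 of the genes with higher and 0 of those with lower counts did the counting interval lie wholly beyond 2-fold. With at least 1000 reads required the counts were 3 and 0, and with at least 20 reads 156 and 219, so most calls came from genes with few reads. The standard deviation of the log2 ratio among genes of 1000 to 10000 reads was 0.170, against 0.045 from counting alone, a spread that 1 library per condition cannot divide between treatment and culture.

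**Figure D1:**
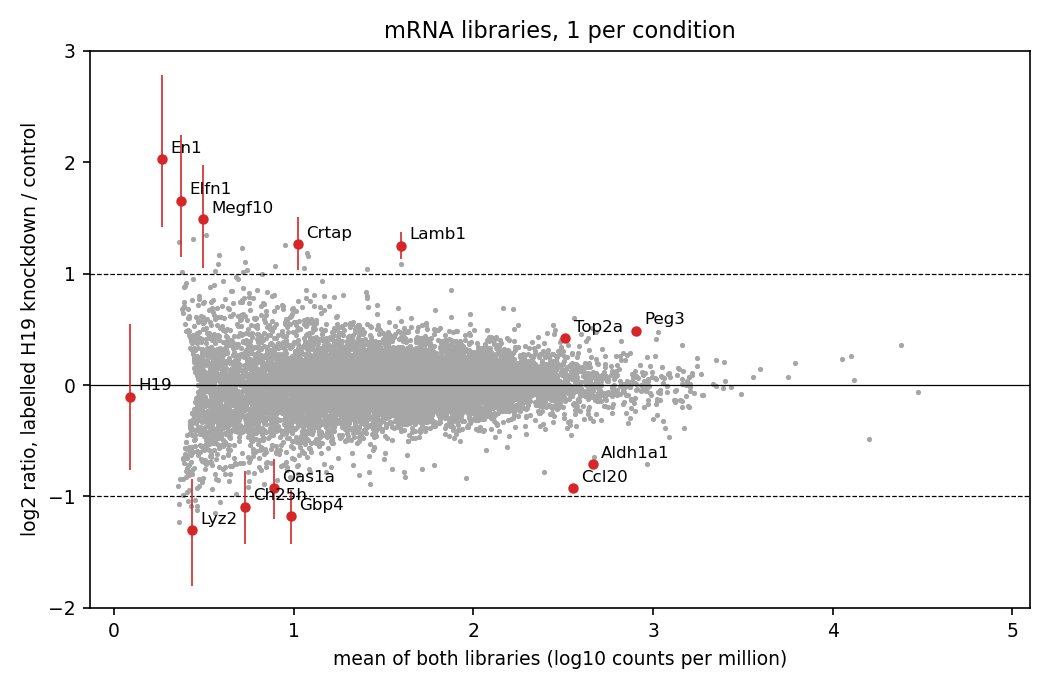
Log2 ratio of the library labelled H19 knockdown over control (vertical) against mean abundance in log10 CPM (horizontal), 1 library per condition; gray points are genes with at least 100 reads in 1 library, red points are selected genes with 95% counting intervals, and dashed lines mark 2-fold. H19 lies near 0 at a log2 ratio of -0.10, and En1 is highest at 2.03.

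Of 29 gene lists with a percentile, 13 lay outside the range of random lists. Independent lists of unrelated genes would give 1.5. Some lists share members and genes of a list may vary together, so 1.5 is not the number expected by chance here. The interferon response list was lower in the library labelled H19 knockdown: 35 of 37 members were below 0, 3 at least 2-fold and 12 at least 1.5-fold, and its median log2 ratio of -0.40 lay below all 10000 random lists. Oas1a, an oligoadenylate synthetase, had 343 and 180 reads (log2 ratio -0.93), Ifi47 683 and 410 (-0.74) and Oas3 312 and 192 (-0.70). In the same library 5 of 6 macrophage genes were below 0 at a median of -0.38, as were 3 of 3 measured lymphocyte genes at a median of -0.39. The lymphocyte list names 13 genes, and 3 measured members were too few for a percentile. Reads were 3189 and 2417 for Cd14, 118 and 140 for Cd68 and 202 and 98 for the 4 other macrophage genes together. Of these 4, Lyz2 had 132 and 53 reads. Cd74, counted below 0 and chosen after its value was seen, had 14 and 14. With at least 1000 reads required the interferon median was -0.17, still at a percentile of 0.06. The inflammatory chemokine and cytokine list had a median of -0.21, below all random lists, with 21 of 28 members below 0. The chemokine Ccl20 had 15836 and 8349 reads (-0.93), Saa2 had 136 and 76 (-0.83), and the adhesion molecule Icam1 had 2187 and 1301 (-0.75).

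The unfolded protein and amino acid stress list was lower, with 19 of 22 members below 0, a median of -0.13 and a percentile of 0.02. Hspa5, the main chaperone of the endoplasmic reticulum, had 57044 and 43749 reads (-0.38), and Chac1 had 530 and 370 (-0.52). Of the p53 targets and cell cycle inhibitors 17 of 24 were below 0, with a median of -0.11 and a percentile of 0.07. Eda2r was at -0.63 and Fas at -0.46, while Gdf15 was at 0.50. The hepatocyte differentiation list had 17 of 23 members below 0, a median of -0.20 and a percentile of 1.33, or 3.24 with the mean in place of the median. Alb was at -0.55 with 129 and 88 reads and Apob at -0.30 with 37279 and 30259, while Cebpa was at 0.35.

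Cell cycle genes were higher in the library labelled H19 knockdown. Of 38 members 35 were above 0, with a median of 0.26 above all 10000 random lists, and 1 was at least 1.5-fold higher. Bub1b, of the spindle checkpoint, had 2019 and 3078 reads (0.61), the replicative helicase subunit Mcm4 had 3345 and 4708 (0.49) and Top2a, topoisomerase II alpha, had 9408 and 12614 (0.42). The extracellular matrix list had 20 of 27 members above 0 and a median of 0.21, above all random lists. Among members with at least 100 reads the basement membrane genes Col4a1 (3779 and 6100 reads, 0.69), Nid1 (4308 and 6900, 0.68) and Col4a2 (1595 and 2551, 0.68) followed Lamb1. The mesenchymal list had 13 of 17 members above 0, a median of 0.25 and a percentile of 99.92, with S100a4 at 0.61 and Sparc at 0.35 but Itgb3 at -0.37.

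Wnt target genes had a median of 0.26 (percentile 99.91, 10 of 13 above 0), with Znrf3 at 0.28 and Glul at 0.26 but Bambi at -0.26. With at least 1000 reads required the percentile was 71.1, inside the random range. Cholesterol synthesis genes had a median of 0.13 (percentile 99.62, 18 of 23 above 0), among them Mvk, mevalonate kinase, at 0.36 with 806 and 1033 reads and Sqle, squalene epoxidase, at 0.33 with 2541 and 3195. Reported miR-675 targets had a median of 0.14 (percentile 98.7, 9 of 13 above 0), with Cdc6, also in the cell cycle list, at 0.42. No read of miR-675 itself was listed in either small RNA library. The percentile of its targets was 69.4 with at least 1000 reads, 95.7 with the mean and 91.2 with chromosome medians subtracted. The small RNA pathway list had a median of 0.12 (percentile 98.6, 14 of 19 above 0), with Dicer1 highest among members with at least 100 reads at 0.50. Its percentiles were 95.8 and 93.0 at minimums of 20 and 1000 reads in 1 library. Among the signs of RNA quality, mitochondrially encoded genes had a median of 0.35 above all random lists, with 8 of 9 above 0 and mt-Nd2 at 0.54. This difference accompanies each gene group described here.

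The other lists lay inside the random range. The median was 0.01 for the imprinted gene network (percentile 57.2), with 7 members above and 7 below 0. In it Peg3 had 22525 and 31602 reads (0.49) and Snrpn 255 and 181 (-0.49). For fetal liver and progenitor markers, in which Aldh1a1 was at -0.71 and Krt19 at 0.42, the median was 0.02 (60.6). It was 0.12 for pluripotency and stemness factors (93.2), 0.01 for the TGF-beta list (45.6), -0.12 for epithelial genes (3.75), 0.03 for let-7 targets (68.7), 0.04 for Hippo-YAP targets (69.0), 0.07 for fatty acid and lipid metabolism (90.0), -0.01 for glycolysis and hypoxia (25.1) and 0.02 for NRF2 and xenobiotic response (57.0). Immediate early genes had a median of -0.04 (31.3), heat shock genes 0.00 (42.3) and housekeeping genes 0.00 (35.0). Of markers of other cells, macrophage genes had a median of -0.38 over 6 members (5.0), cholangiocyte genes 0.01 (53.6) and endothelial genes 0.00 over 5 (53.7). Some of these lists passed the limit under other settings. Epithelial genes were at percentiles of 0.70 and 0.03 with minimums of 20 and 1000 reads and 0.81 with chromosome medians subtracted. Pluripotency factors were at 99.4 with a minimum of 20 reads and 99.0 with chromosome medians subtracted, let-7 targets at 98.7 with a minimum of 1000 reads and 99.6 with chromosome medians subtracted, and macrophage genes at 1.45 with the mean. Lists of fewer measured members had medians of -0.39 for 3 lymphocyte genes, -0.46 for 4 stellate cell and fibroblast genes and -0.67 for 1 erythroid gene.

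**Figure D2:**
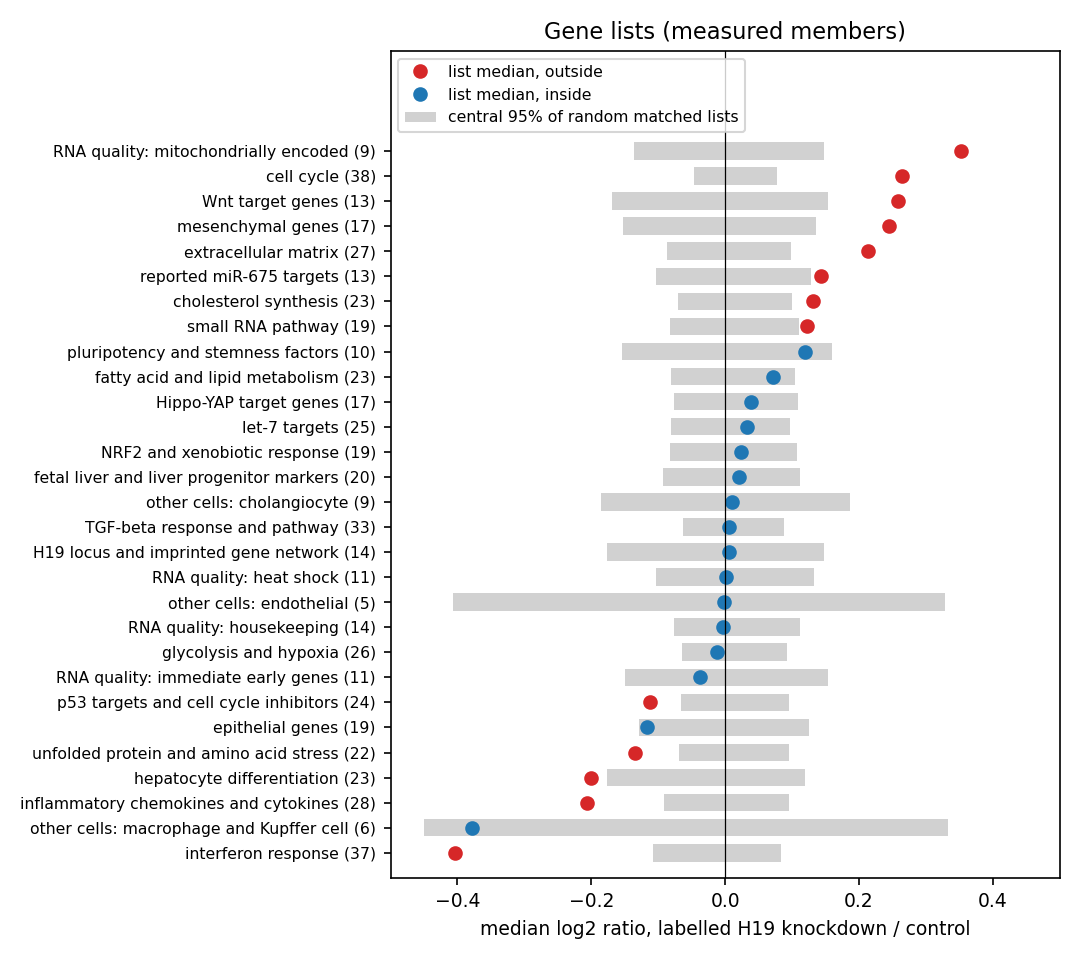
Median log2 ratio of the library labelled H19 knockdown over control for each gene list with at least 5 measured members, with their number; gray bars span the central 95% of random expression-matched lists, and red points lie outside them. The interferon response is lowest at -0.40 and the mitochondrially encoded list highest at 0.35.

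Chromosomes were compared after the data had been seen. Genes of chromosome 12 had a median log2 ratio of 0.28 over 369 genes, 91.1% of them above 0, and genes of chromosome 4 had a median of -0.17 over 670 genes, 14.8% of them above 0. Chromosome 6 was at -0.10 and chromosome 19 at -0.09, and chromosome X at 0.07. Lamb1, Flrt2, Eml1 and Dicer1 lie on chromosome 12, and Camta1 on chromosome 4. With each gene's chromosome median subtracted 20 genes were at least 2-fold higher and 11 lower, and the interferon median was -0.41. Lamb1, Flrt2 and Camta1 then no longer reached 2-fold, while Eml1 did.

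**Figure D3:**
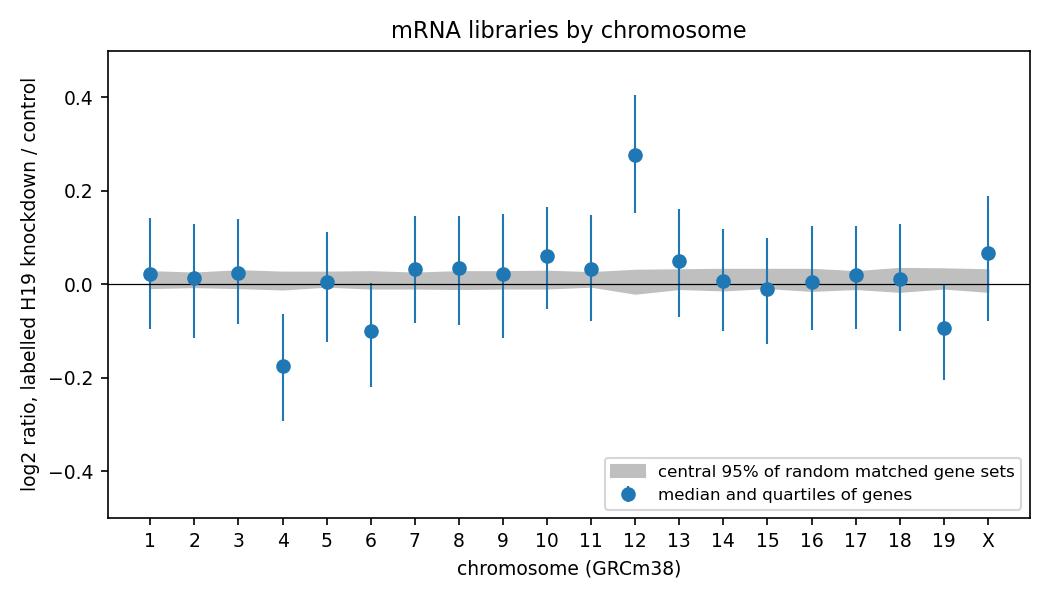
Median log2 ratio of the library labelled H19 knockdown over control for genes of each GRCm38 chromosome with at least 100 reads in 1 library; bars are quartiles over genes and the gray band spans the central 95% of random expression-matched gene sets. Chromosome 12 lies highest at 0.28 and chromosome 4 lowest at -0.17.

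The small RNA comparison asked which miRNAs differ with the H19 hairpin. Of 295 arms 0 were at least 2-fold higher and 6 at least 2-fold lower in the library labelled H19 knockdown. These were miR-6481-3p (217 and 64 reads, ratio 0.210), miR-5112-5p (3673 and 1213, 0.232), miR-6238-3p (202 and 74, 0.260), miR-690-3p (6192 and 2565, 0.291), miR-2137-3p (1387 and 827, 0.419) and miR-3470b-5p (120 and 74, 0.437). The share of precursor reads outside both arms was 94.6% for miR-3470b, 89.5% for miR-690, 77.6% for miR-6481, 77.5% for miR-6238, 43.6% for miR-5112 and 16.5% for miR-2137. With exact matches to the mature sequence alone 1 arm was at least 2-fold lower. At 1.5-fold, 8 arms were higher and 15 lower. The highest ratios included miR-504-5p at 1.95 (259 and 720 reads), miR-1843b-3p at 1.75, miR-411-5p at 1.66 and miR-200b-3p at 1.60.

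The most abundant miRNAs differed little. The ratio was 1.13 for miR-22-3p, with 27.5% of arm reads in the control and 29.9% in the library labelled H19 knockdown, and 0.963 for miR-21a-5p, with 20.4% and 18.9%. It was 0.803 for miR-10b-5p. Among let-7 miRNAs, let-7f-5p had 50038 and 94770 reads (ratio 1.33), let-7c-5p 18347 and 34225 (1.31), let-7i-5p 1.23, let-7b-5p 1.24 and let-7a-5p 1.00. The summed reads of the 9 let-7 and miR-98 5p arms with at least 1000 reads were 1.20-fold higher, and 8 of them lay above 0, or 6 when scaled to the total count. Of the miR-17 cluster and its paralogs miR-18a-5p was at 0.620, miR-19a-3p at 0.641 and miR-19b-3p at 0.729, while miR-93-3p was at 1.62 and 10 of 17 arms lay above 0, or 8 when scaled to the total count.

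Of 17 miRNA lists with a percentile 0 lay outside the random range. The median log2 ratio was 0.17 for let-7 and miR-98 (percentile 96.8), 0.02 for miR-17~92 and paralogs (42.4), -0.14 for miR-34 (15.7), 0.02 for miR-29 (62.0), 0.06 for miR-30 (70.6), -0.11 for miR-15 with miR-16 (32.7), 0.19 for miR-181 (87.3), 0.02 for miR-26 and miR-27 (53.6), -0.23 for miR-23 with miR-24 (8.68) and -0.22 for miR-148 with miR-152 (6.13). It was -0.15 for the X-linked miR-322 and miR-503 cluster (22.5), 0.27 for the Dlk1-Dio3 cluster (93.5), -0.01 for the Sfmbt2 cluster (46.5), -0.13 for hepatocyte miRNAs (17.1), -0.02 for miRNAs reported to bind H19 (36.9), -0.07 for liver cancer miRNAs (18.9) and -0.07 for blood, endothelial and muscle miRNAs (48.7). The miR-200 family had a median of 0.54 over 4 arms and miR-221 with miR-222 -0.20 over 4. Of the reads of mir-222, 70.2% lay outside both arms, and its precursor total was at 0.245, against -0.311 for mir-221. The let-7 list passed the limit under other settings, at percentiles of 99.1 and 99.98 with minimums of 20 and 1000 reads, 99.8 without a minimum and 98.1 with 10 bins, and the miR-200 family was at 98.05 without a minimum. No arm of miR-483 or of the embryonic stem cell clusters was measured.

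**Figure D4:**
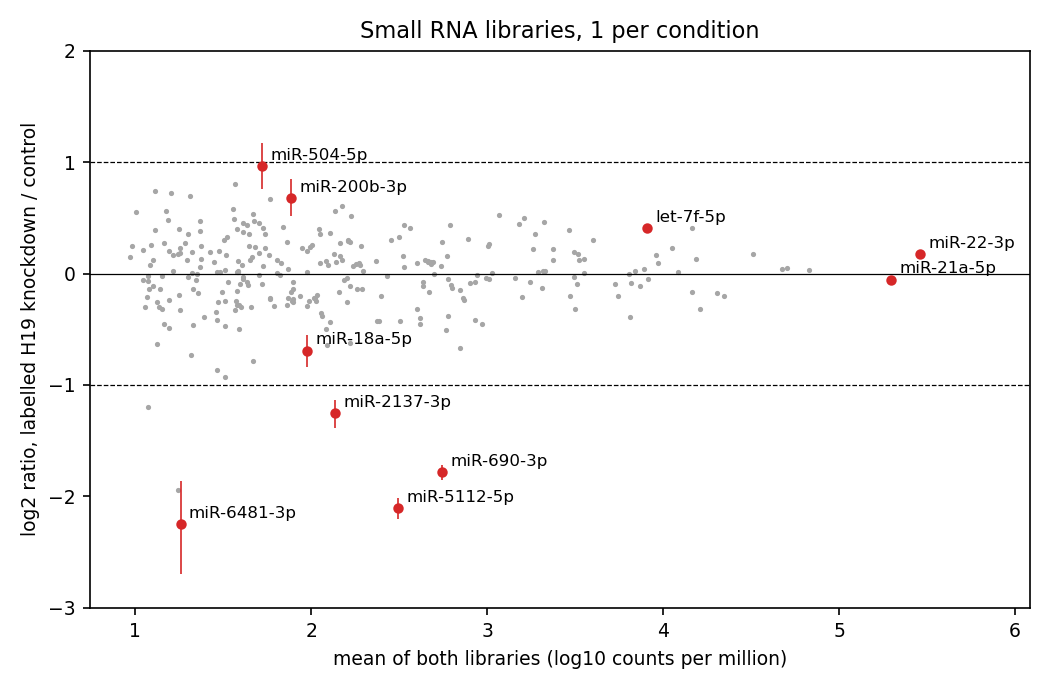
Log2 ratio of the library labelled H19 knockdown over control (vertical) against mean abundance in log10 CPM (horizontal) for mature arms with at least 100 reads in 1 library; red points are selected arms with 95% counting intervals, and dashed lines mark 2-fold. The lowest arm is miR-6481-3p at -2.25.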

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

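Reads outside both mature arms were not part of the main comparison of arms. At the precursor mir-3471-2 there were 35 such reads in the control and 121 in the small RNA library labelled H19 knockdown, a scaled log2 ratio of 1.26, which was flagged because a column left out of that comparison was higher there than in the control. As a share of all reads on precursors such reads were 8.81% in the control and 6.61% in that library, and of 43 precursors with over 50% of reads outside both arms 34 had lower totals there.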

How the results depend on the processing

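The H19 log2 ratio stayed between -0.14 and -0.09 under every alternative run. Scaling and added counts kept the counts of 2-fold genes and arms within 1.5 times. Genes at least 2-fold higher and lower numbered 156 and 219 with a minimum of 20 reads, 3 and 0 with 1000, 220 and 302 without a minimum, 6 and 0 with intervals wholly beyond 2-fold and 150 and 159 at 1.5-fold. Arms higher and lower numbered 6 and 13 with a minimum of 20 reads, 169 and 129 without one and 8 and 15 at 1.5-fold, with 3 lower at 1000 reads. Chosen after seeing the data, exact matches gave 1 lower arm, precursor totals 1 higher and 19 lower, and leaving out precursors read mostly outside their arms 2 lower. Other minimums admit other features; elsewhere the cause was not tested. Gene lists outside the random range numbered 12 to 15 against 13, and miRNA lists 1, 1, 2 and 1 at minimums of 20 and 1000 reads, without a minimum and with 10 bins, against 0. Scaled to the total count, 3 named log2 ratios whose interval excluded 0 changed sign: miR-182-5p to -0.001, miR-27b-3p to -0.019 and miR-30a-5p to -0.008, the cause being the shift of -0.05 between scalings; so did arms whose interval included 0, such as let-7a-5p to -0.047. Of 1259 values of 227 named genes and arms 1184 stayed within their interval, 30 moved up and 42 down. H19 had 43 of 33578868 reads in the control and 40 of 34061172 in the mRNA library labelled H19 knockdown (1.27 and 1.18 CPM). Its level was thus low in both libraries, below the minimum of 100 reads. So few reads widen its counting interval.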

Other observations

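The tests on H19, interferon genes, windows and miRNA arms were chosen after the result was seen; those on GC content, let-7 sites and shuffled motifs were set before. The histone genes, noncoding RNAs and histocompatibility genes named in this paragraph were chosen after their values were seen. Histone genes whose symbols begin with Hist were higher in the library labelled H19 knockdown in 54 of 54 cases, with a median log2 ratio of 0.25. The nuclear noncoding RNAs Malat1 and Neat1 were at -0.49 and -0.38, while Rny1 was at 0.85, Rny3 at 1.09, Rpph1 at 0.36 and Rn7sk at -0.06. Among class I histocompatibility genes H2-Q4 was at -0.89, H2-T22 at -0.47, H2-K1 at -0.27 and H2-D1 at -0.25. The 43 precursors with over 50% of reads outside both arms had a median log2 ratio of -0.72 in total reads. Of these 43, 17 were at least 2-fold lower, against 2 of 231 others. The 43 include copies such as mir-692-2 and mir-692-3, and reads matching several copies are counted at each.

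H19 was not measurably lower in the library labelled H19 knockdown. The upper bound of its log2 ratio was 0.55, which argues against counting error alone hiding swapped labels with a knockdown of at least 2-fold. The lower bound was -0.764, which argues against few reads alone hiding a knockdown of that size. These bounds leave out the spread between cultures, which 1 library per condition cannot give, and reads of overlapping or antisense genes. A knockdown of that size masked by either is not excluded. A weaker knockdown, a wrong label without a partner, or a knockdown lost by the time of harvest stays open and was not tested.

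Interferon genes were lower in the library labelled H19 knockdown. With chromosome medians subtracted the list median was -0.41, so chromosome-wide shifts do not account for it. Fewer leukocytes may underlie it and stay open. Cd14 (3189 and 2417 reads) and Cd68 (118 and 140) were left out as not specific to leukocytes. Of the 6 macrophage genes only Cd68 lay above 0. The 4 other markers had 202 and 98 reads. Lyz2 alone had 132 and 53 of these, so the drop rests mainly on 1 gene. The list had 54274 and 47522 reads, and the markers lost 0.0153 of the reads that the list lost. B2m, also in the housekeeping list, had 27847 and 24897 of the list's reads (log2 ratio -0.16), so the summed reads rest largely on 1 gene. The reads leukocytes would bring to interferon genes are not known here. An effect of the H19 hairpin and a difference between cultures may each underlie the lower interferon genes and were not tested.

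Genes of chromosome 12 were higher and those of chromosome 4 lower. After a fit on GC content, transcript length and expression, with values for 87.9% of their genes, the gap between the medians was 0.459 against 0.452 before, which argues against those trends as the cause. All 27 windows of 10 Mb with at least 10 genes had the sign of their chromosome, between 0.12 and 0.35 on chromosome 12 and between -0.28 and -0.09 on chromosome 4, which argues against a few regions. In the small RNA libraries the gap was 0.36, at percentiles of 96.1 and 4.25 for 11 and 12 arms, too few to decide whether chromosome copy number may have differed between the cells, which stays a candidate explanation. An effect of the hairpin was not tested.

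A hypothesis was that genes with let-7 seed sites would be lower where let-7 reads were higher. The median log2 ratio of 1592 genes with a site in the 3' UTR was 0.011, at the 0.78 percentile of genes matched on expression and 3' UTR length, whose median was 0.023. In a separate draw of 1000 random sets the site lay at the 1.4 percentile, and 1.5% of 200 motifs of the same bases in shuffled order lay as low, which argues against base composition. The values go with slightly lower levels of such genes, but the difference was -0.012. The site test was not repeated with chromosome medians subtracted, and those medians ran from -0.175 on chromosome 4 to 0.276 on chromosome 12. The fixed list of let-7 targets was not lower, with a median of 0.03 at a percentile of 68.7, inside the random range, and 13 members above and 12 below 0. Its median was 0.13 with a minimum of 1000 reads and 0.11 with chromosome medians subtracted, at percentiles of 98.7 and 99.6, so the hypothesis stays weak.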
